A study of Mus musculus with 4 samples.

How the data were processed

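Single-cell RNA was counted in 4 libraries of sorted aortic cells from mice 12 weeks old, 1 library per group, so cells were never treated as replicates. Per the labels' protocols, the tissue was digested with enzymes in the cold, ITGA8-positive cells were sorted, and libraries were made with the 10x Genomics 3′ v3.1 chemistry. Per the file headers, the deposited matrices hold UMI counts, whole numbers per gene and barcode, made with Cell Ranger 7.0.0. Per the submitters' processing notes, reads were aligned to mm10 and later steps used Seurat 4.3, whose output was not used here. The 4040, 8845, 6539 and 10506 barcodes of Root, Asc-GFP, Asc-RFP and Arch-GFP equal the cells stated before filtering in the notes, which state 1841, 4050, 2450 and 4710 after it. Each matrix has 32287 features, eGFP and tdTomato among them. By Ensembl identifier, 32158 were matched to GENCODE M21 for positions on mm10. Whether both strands were counted is not given in the sources used here, so values of antisense genes such as Hand2os1 and Tsix could include reads of the gene opposite.

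Barcodes with at least 1000 detected genes and at most 10% mitochondrial UMIs were kept, 2960, 6408, 4030 and 8031 in the same order. The doublet caller scrublet, run in scanpy at 0.8% expected doublets per 1000 barcodes, called 0, 1, 1 and 0 cells and so has not worked here, and doublets remain in the pooled cells. Possible signs of them were counted instead. Pooled cells with UMIs of both Xist and a Y-linked gene made up 1.93% of Root, 9.47% of Asc-GFP, 5.35% of Asc-RFP and 10.2% of Arch-GFP. Their median UMIs, against those of female and of male cells, were 16302 against 13483 and 13779 in Root, 14612 against 13257 and 13176 in Asc-GFP, 14756 against 14097 and 13876 in Asc-RFP and 12093 against 13323 and 13592 in Arch-GFP. In Arch-GFP they were the shallower cells, so there this sign need not be doublets. In Root, 32 cells (1.15%) held at least 8 eGFP UMIs and more than 1 tdTomato UMI, with a median of 23200 UMIs. Free RNA was not removed.

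Counts were normalised to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at a resolution of 0.5 gave 11 clusters over all libraries, with no integration, seed 1. The comparisons, the rules for named genes and lists and an SMC-like class were written down before the data were examined. Cluster 4 had 3 fibroblast markers and no SMC marker among its 10 leading genes, so the name SMC-like was not used. All 11 clusters had 11 or 12 of 12 SMC markers detected, so clusters were left out by a rule set after they were seen. A cluster was left out if at least 3 markers of another cell type were among its 10 leading genes and its SMC markers had a mean log2 ratio under -1.5 against the other clusters (-1.51 in cluster 8 and -3.30 in cluster 10, and 0.16 in cluster 4). It was also left out if its median UMIs, relative to its libraries, were under 1/3 and no marker type led it (cluster 7). The cells of the 8 remaining clusters are called pooled cells. The other clusters were macrophage-like (cluster 8, 3.34% of Root, 0.0156% of Asc-GFP, 1.64% of Asc-RFP and 0% of Arch-GFP cells, for which 3 counts would be 0.0374%), endothelial-like (cluster 10, 1.82%, 0.0312%, 0.347% and 0%) and an unnamed cluster of low UMIs (cluster 7, 0.541%, 1.19%, 0.546% and 1.01%). Pooled cells had medians of 13416, 13032, 13697 and 12703 UMIs and 3618, 3612, 3653 and 3621 genes, in the order above.

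UMIs were summed over the pooled cells of each library (38224204, 83892697, 53351249 and 100806222 UMIs) and divided by the total to give CPM. Levels have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact binomial intervals, all at 95% and for counting error only, with no spread between animals in them. At 20 CPM or more, the largest Poisson interval had a half-width of 7.25%. A count of 0 was set against 3 counts and given as a bound. Ratios within clusters were handled otherwise: 0.5 UMI was added to each sum, and the log2 ratios were averaged over the clusters. Genes with at least 20 CPM in either library of a comparison entered the counts of genes at least 2-fold higher or lower. Sex-linked genes and the reporters were not kept out of these counts. The main comparisons were Asc-GFP with Asc-RFP, Arch-GFP with Asc-GFP, Root with Asc-RFP and Arch-GFP with Root, and Root with Asc-GFP and Arch-GFP with Asc-RFP were given as counts and lists.

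Named genes followed a fixed rule: genes with at least 20 CPM in either library were ranked by the bound of the interval nearest 0, and the 12 highest and 12 lowest of each comparison were named (6 and 6 for Arch-GFP against Root), leaving out mitochondrial and ribosomal protein genes, Xist, Tsix and Y-linked genes. From each of 25 gene lists, up to 4 members with the largest ratios were named. Some genes that these rules name are not reported here. A list member was measured at 5 CPM or more in either library, and the percentile set the list's median among 10000 random lists drawn from genes within 100 ranks of expression. Female cells had at least 1 Xist UMI and no UMI of Ddx3y, Eif2s3y, Kdm5d or Uty, and male cells the reverse. In Root, eGFP cells had at least 8 eGFP UMIs and at most 1 tdTomato UMI (574 cells), and tdTomato cells had tdTomato and at most 2 eGFP UMIs (1935 cells). For shares of cells with a UMI and for the score per cell, cells were thinned to 4100 UMIs, which left out 65, 231, 361 and 753 shallower cells.

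The procedure was tested on simulated data made from the real totals of each main comparison, with 50 genes each set to 1.5-, 2-, 3- and 4-fold. The rule called 0 of 50 at 1.5-fold and 50 of 50 at 3- and at 4-fold in every comparison. At 2-fold it called 24, 28, 27 and 27 of 50 for Asc-GFP with Asc-RFP, Arch-GFP with Asc-GFP, Root with Asc-RFP and Arch-GFP with Root, and it called no gene without a set difference. The intervals covered the set ratio for 95.0%, 95.1%, 94.7% and 95.0% of genes. The simulated counts varied by Poisson counting error only, with no spread between animals or cell mixes. These figures therefore check the arithmetic and say nothing about calls that such spread would make. Alternatives written beforehand were other barcode filters, doublets kept, all classes of cells, other scalings (edgeR TMM and DESeq2 factors, totals without mitochondrial and ribosomal genes, cells weighted equally), other floors, thinned cells, ratios within clusters and a Leiden resolution of 1.0. Scalings by TMM, DESeq2 and reduced totals shifted ratios by 0.000547 to 0.0568 in log2. Alternatives by sex, by cluster and by Root reporter were added after the data were seen.

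Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.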

Results

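Cells of the mouse aorta, sorted for smooth muscle cells (SMCs), were profiled by droplet-based single-cell RNA-seq, which counts the 3′ ends of transcripts with unique molecular identifiers (UMIs), in 4 libraries from animals 12 weeks old. The animals carried Wnt1-Cre2, a recombinase driver active in the neural crest, together with the mT/mG reporter. In this reporter a recombined cell and its descendants make membrane eGFP, and every other cell makes membrane tdTomato. ITGA8, an integrin subunit on the surface of SMCs, was the sorting antigen. The libraries were the aortic root (Root, whose title gives no reporter colour), the GFP and RFP (tdTomato) cells of the ascending aorta (Asc-GFP and Asc-RFP) and the GFP cells of the aortic arch (Arch-GFP). By its title, the series is about aortic SMCs of cardiac and of neural crest descent. The comparisons set the sorted cells by reporter colour within the ascending aorta and by segment. Only Arch-GFP and Asc-GFP share a colour across segments, since Root held cells of both, so that in the comparisons with Root segment and reporter are mixed.

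Root held 4040 barcodes with 41479646 UMIs in total, Asc-GFP 8845 with 87500240, Asc-RFP 6539 with 57063251 and Arch-GFP 10506 with 104691850. Each group was 1 library, so no difference below has a replicate check, and all intervals are 95% intervals that cover counting error only. Levels are UMIs summed over the pooled cells of a library and scaled to CPM, and ratios are log2 ratios of CPM. In a gene list, a member counted as higher or lower at a log2 ratio of at least 0.5 in size and as within otherwise, and the percentile ranks the list's median among random lists of like expression. Random lists were drawn gene by gene, while members of a list may vary together, so the percentile is a description and not a test. Extreme percentiles came with small medians too, as percentile 0 at -0.094 for contractile genes in Asc-GFP against Asc-RFP. The pooled cells numbered 2791 in Root, 6328 in Asc-GFP, 3927 in Asc-RFP and 7950 in Arch-GFP, or 94.3% (93.4 to 95.1), 98.8% (98.5 to 99.0), 97.5% (96.9 to 97.9) and 99.0% (98.7 to 99.2) of the cells kept by the quality filter.

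The contractile genes Acta2 and Myh11 were abundant in all 4 libraries. Acta2, the smooth muscle actin, stood at 19128 CPM (19085 to 19172) in Root, 23687 CPM (23654 to 23719.9) in Asc-GFP, 24827 CPM (24785 to 24869.6) in Asc-RFP and 21354 CPM (21326 to 21383) in Arch-GFP. The summed level of 12 SMC markers ranged from 44084 CPM in Arch-GFP to 50941 CPM in Asc-RFP. The libraries filled different clusters: cluster 4 held 1639 of the pooled Root cells and cluster 2 held 3003 of the Asc-RFP cells. Asc-GFP cells lay mostly in clusters 1, 0 and 3 (2530, 1976 and 1029 cells) and Arch-GFP cells in clusters 0, 3, 6 and 1 (3203, 2096, 1152 and 1146 cells). Cluster 0 was led by the Y-linked genes Ddx3y and Eif2s3y and cluster 1 by Xist and Tsix, so their filling also follows the mix of sexes given below. Because a cluster filled mostly by 1 library can be that library rather than a cell type, ratios and list medians were also computed within the clusters that hold at least 100 cells of both libraries. For Asc-GFP with Asc-RFP these were clusters 0, 1 and 5, with 212, 127 and 387 Asc-RFP cells. Cluster 2, led by Des, tdTomato and Psd, was left out. For Arch-GFP with Root they were clusters 1 and 5, with 199 and 443 Root cells. In both, the values thus rest on the fewer cells that cluster with the other library, partly by the genes being compared. Cluster 5, shared in every comparison, was led by Fosb, Fos, Atf3 and Egr1, so medians of immediate-early genes within clusters partly follow from how it was built. The 0.5 UMI added to each sum within clusters can by itself make such ratios smaller for genes with few UMIs in a library. Ratios and medians within shared clusters stand in square brackets beside a printed value from which they differ in sign or by over 1.5 times. By the same rule, "at 20 CPM" gives a list's median over members with at least 20 CPM. Medians under 0.05 in both settings were left without either. The values in female and male cells, marked F and M, follow a ratio or median from which 1 of them differs by that rule and by at least 0.1. The male values of Root come from only 297 cells.

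The reporters checked the labels. eGFP was at 3678 CPM in Asc-GFP and 3841 CPM in Arch-GFP but at 16.3 CPM in Asc-RFP, whereas tdTomato was at 429 CPM in Asc-RFP and at 0.155 and 0.0397 CPM in the GFP libraries. Root held both reporters, eGFP at 819 and tdTomato at 318 CPM. At least 8 eGFP UMIs were present in 606 Root cells (21.7%, 20.2 to 23.3), 6266 Asc-GFP cells, 1 Asc-RFP cell and 7808 Arch-GFP cells. The libraries also mixed female and male cells in different shares. By Xist, the RNA of the inactive X chromosome, against 4 Y-linked genes, female cells made up 88.7% (87.4 to 89.9) of the sexed cells in Root, 70.0% (68.7 to 71.2) in Asc-GFP, 54.4% (52.7 to 56.1) in Asc-RFP and 28.8% (27.7 to 30.001) in Arch-GFP. The sex of the animals is not given in the sources used here, so ratios were also computed in cells of each sex.

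**Figure D1:**
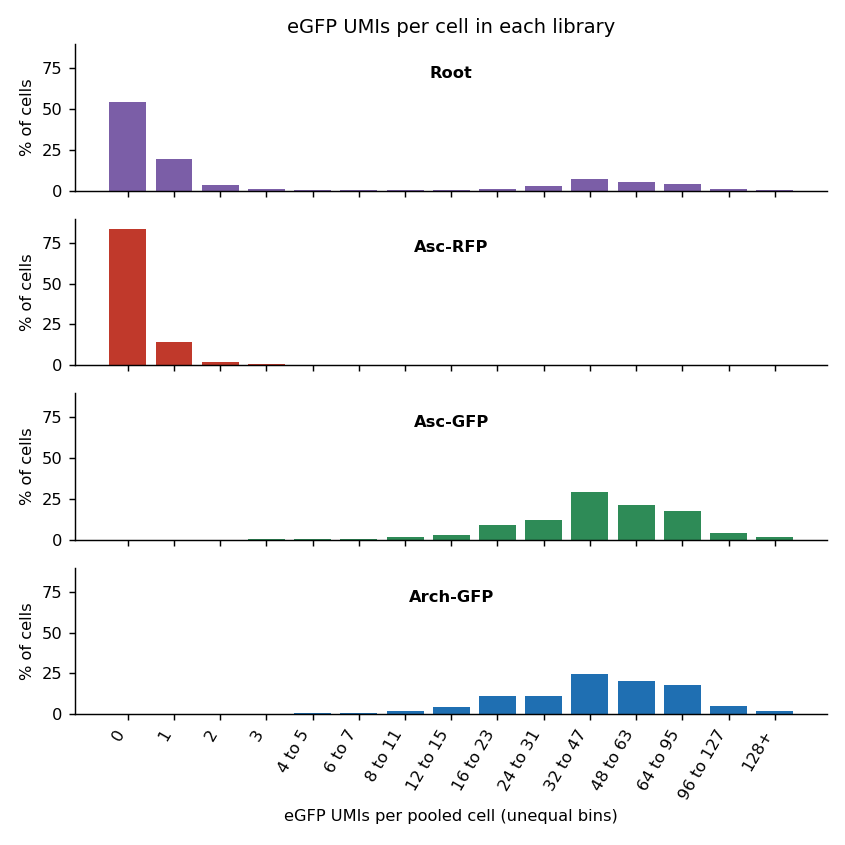
Percent of pooled cells (vertical axis) by eGFP UMIs per cell (horizontal axis, binned), 1 panel per library. Nearly all Asc-GFP and Arch-GFP cells carried at least 8 eGFP UMIs and nearly all Asc-RFP cells fewer, while Root had both kinds, with 21.7% of its cells at 8 or more.

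Within the ascending aorta, among genes with at least 20 CPM in either library, those ranked farthest apart between GFP and RFP cells, after the reporters, were Psd, Des and Tnnt2. Psd, an exchange factor for ARF GTPases, was at 4.76 against 60.5 CPM (log2 ratio -3.67 (-3.82 to -3.52) [-1.60]), Des, the muscle intermediate filament desmin, at 44.9 against 335 CPM (-2.90 (-2.95 to -2.85) [-1.64]) and Tnnt2, cardiac troponin T, at 58.8 against 342 CPM (-2.54 (-2.59 to -2.49) [-1.31]), all lower in Asc-GFP. Higher in Asc-GFP were Ccn5, a matricellular protein (89.6 against 21.1 CPM, 2.09 (1.997 to 2.18) [1.26]), Mia, a small secreted protein (53.3 against 15.3 CPM, 1.80 (1.69 to 1.91)), the keratin Krt18 (1.61) and Acan, the cartilage proteoglycan aggrecan (44.1 against 14.4 CPM, 1.61 (1.498 to 1.72) [0.66]). In mm10 coordinates of GENCODE M21, the protein-coding genes Psd (ENSMUSG00000037126, chromosome 19, 46312087 to 46327156), Tnnt2 (ENSMUSG00000026414, chromosome 1, 135836354 to 135852260) and Ccn5 (ENSMUSG00000027656, chromosome 2, 163820861 to 163833146) were matched by their identifiers. In all, 13 of 5707 genes with at least 20 CPM in either library were at least 2-fold higher in Asc-GFP and 16 at least 2-fold lower, the reporters eGFP (7.82) and tdTomato (-11.43) among them.

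Other named genes higher in Asc-GFP were Epas1, a hypoxia-inducible transcription factor (98.04 against 36.2 CPM, 1.44 [0.80]), the cardiac T-box factor Tbx20 (1.25 [0.74]), the endothelial adhesion gene Pecam1 (26.2 against 11.5 CPM, 1.18 [0.36]), Emb (1.17 [0.42]), Gm26771 (1.15 [0.41]), Hacd4 (1.08) and 4631405J19Rik (1.06 [0.71]). The summed endothelial markers, which include Pecam1 and so are no separate sign, stood at 52.5 CPM in Asc-GFP and 36.9 CPM in Asc-RFP. Lower were the glypican Gpc3 (13.4 against 57.2 CPM, -2.09 [-1.02]), Hand2os1 (-1.89), an RNA transcribed beside the heart regulator Hand2, decorin (Dcn, 15.7 against 56.3 CPM, -1.84 [-1.15]), the DNA damage kinase Chek2 (-1.60 [-0.70]), ceruloplasmin (Cp, -1.51 [-0.71]), the collagen cross-linker Loxl2 (-1.45 [-0.95]), Zfp503 (-1.38 [-0.90]) and Cgnl1 (-1.28 [-0.21]). Summed fibroblast markers were close, at 1099.9 and 1011 CPM.

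Among the regulators associated with the heart and second heart field, 2 of 13 measured members were higher, 5 lower and 6 within that size, with a median of 0.024 [-0.051], -0.090 at 20 CPM, F 0.031, M -0.080, percentile 48.9 of random lists. Besides Tnnt2 and Tbx20, Nr2f1, a nuclear receptor, was at 9.69 against 2.74 CPM (1.82 (1.57 to 2.09)). The summed cardiomyocyte markers, which include Tnnt2, were at 131 CPM in Asc-GFP and 414 CPM in Asc-RFP. Of the genes of modulated SMCs, 0 of 14 measured members were higher, 4 lower and 10 within that size (median -0.14 [-0.26], F -0.032, M -0.25, percentile 0), led by Col8a1 (2.97 against 12.1 CPM), Lum (1.64 against 6.41 CPM) and Thbs1 (2.88 against 10.5 CPM). The contractile apparatus had 0 higher, 2 lower and 23 within of 25 (median -0.094 [0.015], percentile 0), with Des and phospholamban (Pln, -0.77 [-0.39]) lower, and of its regulators none of 13 reached the size of 0.5 (median 0.029 [-0.085], percentile 67.3). Proteoglycan and cartilage-type matrix genes were split, 2 higher, 3 lower and 7 within of 12 (median 0.075 [0.017], 0.047 at 20 CPM, percentile 96.8), with Comp (13.9 against 2.57 CPM, 2.43 (2.17 to 2.70) [1.32]) and Acan higher and Lum (-1.96 [-3.52]) and Dcn lower. For collagens the counts were 0 higher, 3 lower and 14 within of 17 (median -0.054 [-0.028], percentile 0.230).

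BMP genes were 3 higher, 1 lower and 13 within of 17 (median 0.11 [0.021], 0.044 at 20 CPM, percentile 99.95), with Fst, the activin antagonist follistatin (0.91, F 0.73, M 1.40), and Id4 (92.2 against 56.2 CPM) higher. For Wnt genes the counts were 4 higher, 1 lower and 16 within of 21 (median 0.079, percentile 99.1), with Ccn5 and the antagonists Sfrp2 (249.8 against 146 CPM) and Wif1 (203 against 129.7 CPM) higher and Frzb (-0.83 [-0.54], F -0.86, M -1.36) lower. Neural crest-associated regulators had 2 higher, 1 lower and 10 within of 13 (median 0.18 [0.070], percentile 100), with Snai2 (0.78 [0.48]) and Prrx2 (0.76) higher and Twist1 (27.2 against 48.5 CPM) lower. The 6 measured HOX genes, which set position along the body, were all within the size (median -0.10, 0.086 at 20 CPM, F -0.083, M -0.21, percentile 1.30). Notch genes gave 1 higher, 0 lower and 6 within of 7 (median 0.14 [0.038], percentile 99.8, Notch3 0.77 [0.51]). Lipid and adipose-type genes gave 2 higher, 1 lower and 7 within of 10 (median 0.20, percentile 99.99, Fabp4 0.93 [0.20]). Growth factor genes of the IGF, FGF and PDGF families had 1 higher, 3 lower and 10 within of 14 (median 0.023, percentile 46.4, Igfbp2 -1.06 [-0.36]). Immediate-early and dissociation genes gave 1 higher, 1 lower and 21 within of 23 (median -0.15 [-0.10], percentile 0, Fos -0.56 [-0.027], F -0.43, M -0.87).

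In the inflammatory list, 0 of 8 measured members were higher, 2 lower and 6 within that size (median -0.10, percentile 0.340), with Cxcl12, a chemokine, at 27.0 against 49.3 CPM. Complement C3 had 1 UMI in Asc-GFP against 8.17 CPM in Asc-RFP (-9.42 (-14.73 to -6.94) [-2.68], M -2.75), and the summed mesothelial markers were at 0.0238 against 4.85 CPM. Vasoactive receptors had 1 higher, 0 lower and 11 within of 12 (median 0.11 [-0.0049], percentile 99.6). Ion channels had 1 higher, 0 lower and 16 within of 17 (median 0.054, percentile 88.3). Axon guidance genes gave 0 higher, 2 lower and 17 within of 19 (median 0.091 [0.014], 0.20 at 20 CPM, percentile 99.1). Matrix proteases gave 1 higher, 1 lower and 12 within of 14 (median -0.026 [-0.087], percentile 3.40). None of 26 oxidative phosphorylation genes (median -0.0052) and 14 circadian genes (median -0.0026) reached the size. The medians of the elastic fibre (0.021, 0.11 at 20 CPM, 0 higher, 2 lower and 16 within of 18), TGF-beta (0.0042 [-0.059], 1 higher, 3 lower and 22 within of 26) and heritable aortic disease lists (0.00097, 0 higher, 1 lower and 19 within of 20) turned negative under another scaling. Elastin itself (Eln) was at 2271 against 1673 CPM (0.44 (0.43 to 0.45) [0.17], F 0.54, M 0.27). The sex-linked list (0 higher, 2 lower and 4 within of 6, median -0.36 [0.13], -0.10 at 20 CPM) followed the larger share of male cells in Asc-RFP.

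Psd carried at least 1 UMI in 2.08% (1.74 to 2.47) of Asc-GFP cells and 18.8% (17.5 to 20.1) of Asc-RFP cells thinned to 4100 UMIs, and in 5.37% and 37.4% of cells as deposited, at median depths of 13032 and 13697 UMIs. The share was 8.08% in 99 macrophage-like Root cells at a median of 8285 UMIs, which sets no background for Asc-GFP, a library with 1 such cell. Within the 3 shared clusters 6 genes were at least 2-fold higher and 7 lower.

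Between the arch and the ascending aorta, both GFP libraries, the genes of at least 20 CPM ranked highest in the arch were Adamtsl1, Prss12 and Fbln1. Adamtsl1, a secreted ADAMTS-like glycoprotein, was at 45.9 against 0.930 CPM (5.62 (5.30 to 5.97) [2.87]), the serine protease Prss12 at 24.5 against 1.01 CPM (4.60 (4.28 to 4.92) [2.26]) and fibulin-1 (Fbln1), a matrix glycoprotein, at 41.6 against 2.16 CPM (4.27 (4.05 to 4.49) [2.45]). Rgs5, a regulator of G protein signalling, was at 349 against 100.7 CPM (1.79 (1.76 to 1.83) [0.50]). Lower in the arch were Tnnt2 at 19.2 against 58.8 CPM (-1.62 (-1.69 to -1.54)), Tbx20 (-1.13) and the ligand Wnt16 at 67.0 against 137 CPM (-1.04 (-1.08 to -0.99)). By the rule of size, 20 of 5790 genes were at least 2-fold higher in Arch-GFP and 6 at least 2-fold lower, with sex-linked genes not kept out. Adamtsl1 (ENSMUSG00000066113, chromosome 4, 85514172 to 86428385) and Rgs5 (ENSMUSG00000026678, chromosome 1, 169655501 to 169695813) are protein-coding.

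Also higher in the arch were the zinc finger gene Tshz2 (3.33 [1.09]), the ephrin receptor Epha3 (22.5 against 2.68 CPM, 3.07), the homeobox gene Prrx2 (44.5 against 6.87 CPM, 2.70 [1.13]), the Wnt antagonist Frzb (40.5 against 6.25 CPM, 2.70), midkine (Mdk, 1.81 [0.54]), Igfbp5 (1.57), Ablim1 (1.51) and thrombomodulin (Thbd, 1.44 [0.81]). The lowest-ranked genes of the rule after Tnnt2, Tbx20, Wnt16 and Bex4 (-1.06) stayed under 2-fold: Krt18 (-0.88), asporin (Aspn, -0.86 [-0.44], F -0.46, M -0.68), Des (-0.73 [-0.41]), Rapgef5 (-0.71), Slc15a2 (-0.70), Fos (-0.67 [-0.24]), Pcsk5 (-0.67, F -1.02, M -0.35) and Emb (-0.63, F -0.999, M -0.57). The summed pericyte markers, which include Rgs5, were at 849 CPM in Arch-GFP and 591 CPM in Asc-GFP.

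Neural crest-associated regulators were higher in the arch or within: 9 of 19 measured members were higher, 0 lower and 10 within that size (median 0.39 [0.15], 0.21 at 20 CPM, percentile 100). Tfap2b, an AP-2 transcription factor, was at 7.06 against 0.0477 CPM (7.21 (5.85 to 9.09) [3.56]), Msx2 at 8.95 against 0.370 CPM (4.60 (4.08 to 5.16) [2.20]), Dlx6 at 18.1 against 1.39 CPM (3.70 (3.43 to 3.98) [1.89]) and Dlx5 at 19.5 against 2.59 CPM (2.91 (2.71 to 3.12) [1.21]). In the elastic fibre list, 4 of 18 measured members were higher, 0 lower and 14 within that size (median 0.19, 0.11 at 20 CPM, percentile 100), with Ltbp2 (82.7 against 42.9 CPM) higher besides Fbln1. Vasoactive receptors had 3 higher, 1 lower and 10 within of 14 (median 0.092 [-0.0093], -0.041 at 20 CPM, percentile 95.9), with the endothelin receptor Ednra at 9.25 against 2.55 CPM. Axon guidance genes gave 3 higher, 0 lower and 16 within of 19 (median 0.17 [0.059], percentile 100). BMP genes gave 1 higher, 0 lower and 16 within of 17 (median 0.18 [0.043], percentile 100, Chrdl1 1.53). IGF, FGF and PDGF genes had 3 higher, 0 lower and 12 within of 15 (median 0.12 [0.059], 0.026 at 20 CPM, percentile 99.5, Igf1 1.85 [0.37], F 2.97, M 2.23). The cardiac list had 0 higher, 2 lower and 9 within of 11 (median -0.087 [-0.056], percentile 0.0800), beside summed cardiomyocyte markers of 81.3 CPM against 131 CPM.

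The 7 measured HOX genes were within the size (median 0.12 [-0.025], percentile 87.4). Contractile genes gave 2 higher, 2 lower and 21 within of 25 (median -0.044, percentile 2.70), with the actin Actg2 at 434 against 260.2 CPM, and their 13 regulators none outside the size (median 0.063, 0.032 at 20 CPM). Proteoglycan genes had 2 higher, 2 lower and 8 within of 12 (median -0.13, -0.29 at 20 CPM, F -0.021, M -0.15, percentile 0), with the chondrogenic factor Sox9 at 12.8 against 3.02 CPM. Collagens had 1 higher, 0 lower and 15 within of 16 (median 0.077 [0.0083], F 0.065, M 0.22, percentile 99.0). Proteases and inhibitors gave 2 higher, 0 lower and 12 within of 14 (median 0.14 [0.041], F 0.054, M 0.27, percentile 99.98). Modulated SMC genes gave 2 higher, 0 lower and 9 within of 11 (median 0.061 [0.11], 0.32 at 20 CPM, F 0.22, M 0.088). Inflammatory genes had 2 higher, 0 lower and 6 within of 8 (median 0.23, percentile 100). Immediate-early and dissociation genes had 1 higher, 2 lower and 20 within of 23 (median -0.020 [0.14], F 0.059, M 0.19). No member left the size in the TGF-beta (24, median 0.051 [0.020]), heritable aortic disease (21, median 0.048), Notch (8, median -0.025, -0.053 at 20 CPM), lipid (10), circadian (14) and oxidative phosphorylation (26, median -0.00095) lists. The medians of the Wnt (0.018, 3 higher, 2 lower and 17 within of 22), ion channel (0.0059 [-0.10], F -0.12, M 0.012, 2 higher, 0 lower and 16 within of 18), lipid (0.0077 [0.053], F 0.23, M 0.12) and circadian (0.030 [0.11]) lists turned negative under another scaling. The sex-linked list was 4 higher, 2 lower and 0 within of 6 (median 0.93, -0.21 at 20 CPM), beside the larger share of male cells in Arch-GFP.

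After thinning to 4100 UMIs, Adamtsl1 was detected in 12.1% (11.3 to 12.9) of Arch-GFP and 0.295% (0.175 to 0.466) of Asc-GFP cells, and as deposited in 18.2% and 1.01%, at median depths of 12703 and 13032 UMIs. It was seen in 0 of 99 macrophage-like Root cells (median 8285 UMIs), which allows up to 3.03% there and sets no background for Arch-GFP or Asc-GFP, with 0 and 1 such cells. Much of the arch difference came with cluster 6, which held 1152 Arch-GFP and 13 Asc-GFP cells and has Adamtsl1, Prss12, Dlx6 and Tfap2b among its leading genes. Without it 9 genes were at least 2-fold higher, and the ratio was 3.04 for Adamtsl1, 2.44 for Fbln1, 0.45 for Rgs5 and 2.92 for Epha3.

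Root cells, set against the RFP cells of the neighbouring ascending segment, carried more Corin, a membrane protease that activates natriuretic peptides (50.2 against 2.17 CPM, 4.53 (4.26 to 4.81) [1.69]), more of the G protein regulator Rgs17 (28.5 against 2.36 CPM, 3.59 (3.32 to 3.87)) and more apolipoprotein E (Apoe, 583 against 147 CPM, 1.99 (1.95 to 2.03) [1.11]). Tnnt2 was at 876 against 342 CPM (1.36 (1.33 to 1.38) [0.54]). Lower in Root were Tafa1, a secreted chemokine-like protein (5.31 against 27.1 CPM, -2.35 (-2.57 to -2.14)), Rgs5 (25.5 against 116 CPM, -2.19 (-2.29 to -2.09), F -2.002, M -4.49) and the Wnt antagonist Sfrp2 (36.4 against 146 CPM, -2.01 (-2.09 to -1.92)). In total 48 of 5767 genes were at least 2-fold higher in Root and 29 at least 2-fold lower. Corin (ENSMUSG00000005220, chromosome 5, 72300025 to 72504473) is protein-coding.

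Further genes higher in Root were eGFP (5.65), since Root held cells of both reporters, the small proteoglycan lumican (Lum, 42.0 against 6.41 CPM, 2.71 [-0.38]), the Wnt antagonist Sfrp1 (42.3 against 8.77 CPM, 2.27, F 2.67, M 1.44), Arhgdib (2.22 [1.35]), gamma-synuclein (Sncg, 329 against 76.0 CPM, 2.11 [1.08]), Cpne8 (2.23 [1.19]), Cp (87.1 against 22.0 CPM, 1.98 [0.86]), Epas1 (1.91 [0.97]) and Olfml2a (1.95 [1.23]). Lower were Chek2 (-2.23), Clec11a (-1.74), Dlgap1 (-1.68 [-0.93]), the water channel Aqp1 (20.5 against 61.5 CPM, -1.58, F -1.52, M -2.49), Pamr1 (-1.49), tissue plasminogen activator (Plat, -1.39 [-0.78]), Gpsm2 (-1.40) and the retinol carrier Rbp4 (158 against 391 CPM, -1.31, F -1.49, M -2.39). Beside Apoe and Arhgdib, which immune cells also express, summed macrophage markers in the pooled cells were at 15.3 CPM in Root and 6.19 CPM in Asc-RFP.

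Of the HOX genes, 0 of 6 measured members were higher, 5 lower and 1 within that size (median -0.86, percentile 0), with Hoxa5 at 3.82 against 7.68 CPM, Hoxb2 at 16.4 against 31.4 CPM (-0.94 (-1.07 to -0.80)) and Hoxb4 at 9.73 against 18.2 CPM. Of the cardiac regulators, 4 of 15 measured members were higher, 0 lower and 11 within that size (median 0.32, percentile 100), with the zinc finger factor Gata4 at 14.2 against 2.66 CPM (2.41 (2.14 to 2.69)), Tbx20 at 42.1 against 12.4 CPM and Tbx2 (1.14 [0.43], F 1.02, M 1.94). Summed cardiomyocyte markers were at 971 CPM in Root and 414 CPM in Asc-RFP, most of it Tnnt2. Notch genes had 3 higher, 0 lower and 5 within of 8 (median 0.43 [0.24], percentile 100), with the SMC receptor Notch3 at 47.2 against 14.0 CPM (1.75 (1.63 to 1.88) [0.63]). Modulated SMC genes gave 8 higher, 1 lower and 5 within of 14 (median 0.67 [-0.070], percentile 100), with Thbs1 (31.3 against 10.5 CPM), Bmp2 (1.31 [0.57]) and Col8a1 (1.18 [0.21], F 0.93, M 1.81) higher besides Lum. Proteoglycan genes gave 6 higher, 2 lower and 5 within of 13 (median 0.50 [0.077], F 0.40, M 0.33, percentile 100), with Comp (2.61 [1.28]), Acan (1.35) and Dcn (108 against 56.3 CPM) higher. Summed fibroblast markers were no higher in Root, at 991 against 1011 CPM, although cluster 4 supplied 1639 of its 2791 pooled cells. That cluster had 3 fibroblast markers among its 10 leading genes and 7 detected. Its mean log2 ratio of the fibroblast markers, each weighted alike, was 1.48 against the other clusters. It also had 12 SMC markers detected, with a mean log2 ratio of 0.16.

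Elastic fibre genes were mostly lower or within (1 higher, 5 lower and 12 within of 18, median -0.21, F -0.20, M -0.41, percentile 0.0100), as Mfap5, a microfibril protein, at 191 against 425 CPM (-1.16 (-1.20 to -1.12) [-0.75], F -1.30, M -2.21). Collagens had 2 higher, 4 lower and 11 within of 17 (median -0.28 [-0.089], percentile 0), with Col6a2 at 96.5 against 176 CPM. Contractile genes gave 1 higher, 3 lower and 21 within of 25 (median -0.12 [-0.048], F -0.14, M 0.14, percentile 0.110), with Pln, the brake on the calcium pump, at 106 against 31.8 CPM (1.74 (1.66 to 1.82) [0.76]) and Actg2 at 199 against 340.4 CPM. Their regulators had 1 higher, 0 lower and 12 within of 13 (median 0.14 [-0.015], percentile 99.7). TGF-beta genes had 4 higher, 0 lower and 22 within of 26 (median 0.078 [0.019], 0.13 at 20 CPM, percentile 98.5), including the inhibitors Smad6 (1.12 [0.68]) and Smad7 (94.2 against 48.8 CPM). BMP genes had 5 higher, 1 lower and 11 within of 17 (median 0.17 [0.081], percentile 99.9). Wnt genes gave 6 higher, 2 lower and 15 within of 23 (median 0.16, F 0.13, M 0.042, percentile 99.9). Axon guidance genes had 5 higher, 4 lower and 11 within of 20 (median 0.10 [0.023], 0.0061 at 20 CPM, percentile 97.7). Neural crest-associated genes gave 5 higher, 1 lower and 8 within of 14 (median 0.33 [0.14], percentile 100), with Plxna2 at 23.7 against 9.90 CPM and Sema3c lower at 35.0 against 66.2 CPM. Proteases had 4 higher, 2 lower and 9 within of 15 (median 0.085 [0.020], F -0.059, M 0.29). Growth factor genes gave 3 higher, 0 lower and 12 within of 15 (median 0.11 [-0.00019], F 0.28, M 0.19). Vasoactive receptors gave 3 higher, 1 lower and 8 within of 12 (median 0.092 [-0.028], 0.013 at 20 CPM, F -0.028, M -0.073). Ion channels gave 1 higher, 1 lower and 15 within of 17 (median 0.011). The heritable disease list had 2 higher, 1 lower and 18 within of 21 (median 0.011). Inflammatory genes gave 4 higher, 1 lower and 5 within of 10 (median 0.30 [0.18], 0.081 at 20 CPM, F 0.27, M -0.0024, percentile 99.9). Immediate-early and dissociation genes were 5 higher, 0 lower and 18 within of 23 (median 0.25 [0.038], F 0.10, M 0.34, percentile 100), with Jun at 852 against 542 CPM. All 26 oxidative phosphorylation genes stayed within the size (median -0.14 [-0.092], percentile 0.490). The lipid (median -0.0013, 3 higher, 0 lower and 7 within of 10) and circadian lists (median 0.0013, -0.13 at 20 CPM, 2 higher, 0 lower and 12 within of 14) turned sign under another scaling, and the sex-linked list (2 higher, 4 lower and 0 within of 6, median -1.73, -0.53 at 20 CPM) went with the larger female share of Root.

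Corin was detected in 11.6% (10.4 to 12.8) of thinned Root cells and 0.645% (0.409 to 0.966) of thinned Asc-RFP cells, and in 20.2% and 2.06% as deposited (median depths 13416 and 13697 UMIs), against 10.1% of the 99 macrophage-like Root cells as deposited. Cluster 4, led by Corin, Lum and Dcn, held 1639 Root cells and 129 Asc-RFP cells. Without it 22 genes were at least 2-fold higher and 14 lower, Corin had a ratio of 1.60, Apoe 1.02 and Cp 0.46, and Lum turned to -0.27. With only the eGFP cells of Root the ratio was 0.24 for Lum, against 2.73 with its tdTomato cells. By level, Lum was at 7.57 CPM in the eGFP cells, 42.5 CPM in the tdTomato cells and 113 CPM in the 282 Root cells of neither call. With eGFP and with tdTomato cells the ratios were 1.35 and 2.39 for Arhgdib, 1.11 and 2.13 for Cp, -3.80 and -2.02 for Rgs5, -2.76 and -1.61 for Clec11a and -0.98 and -1.82 for Aqp1. Within the 4 shared clusters 13 genes were at least 2-fold higher and 12 lower.

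The outermost segments differed most. Rgs5 was at 349 against 25.5 CPM in Arch-GFP and Root (3.78 (3.68 to 3.87) [2.03], F 3.28, M 6.14), Prrx2 at 44.5 against 1.52 CPM (4.87 (4.50 to 5.27) [1.73]) and Mia at 99.0 against 6.80 CPM (3.86 (3.69 to 4.05) [2.38], F 3.92, M 7.53). Lower in the arch were Corin at 0.198 against 50.2 CPM (-7.98 (-8.70 to -7.35) [-5.14]), Tnnt2 at 19.2 against 876 CPM (-5.51 (-5.58 to -5.45) [-3.41]) and Col8a1, a short-chain collagen, at 1.25 against 27.4 CPM (-4.45 (-4.73 to -4.19) [-2.34]). Of 5910 genes, 91 were at least 2-fold higher in Arch-GFP and 71 at least 2-fold lower. The remaining named genes were Prss12 (5.96 [3.31]), Adamtsl1 (4.37 [1.53], F 5.59, M 2.21) and Gm26771 (4.08), all higher in the arch, and tdTomato (-12.97), Arhgdib (-3.98 [-2.63]) and Cp (-3.73 [-1.78]), all lower.

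Cardiac and second heart field-associated regulators were mostly lower in the arch: 1 of 16 measured members were higher, 10 lower and 5 within that size (median -0.85, -0.40 at 20 CPM, percentile 0). Gata4 had 2 UMIs in the arch against 14.2 CPM in Root (-9.48 (-12.53 to -7.62)), Isl1, a marker of the second heart field, was at 0.347 against 6.23 CPM (-4.16 (-4.72 to -3.65)), and Tcf21, an epicardial factor, with 0 UMIs in the arch and 5.28 CPM in Root, was at least 178-fold lower. Summed cardiomyocyte markers were 81.3 CPM in Arch-GFP and 971 CPM in Root. The HOX genes went the other way, since 5 of 7 measured members were higher, 0 lower and 2 within that size (median 0.90 [0.43], percentile 99.99), with Hoxb2 at 33.5 against 16.4 CPM, Hoxb3 at 10.4 against 5.44 CPM and Hoxa5 at 7.27 against 3.82 CPM. Of the neural crest-associated regulators, 8 of 19 measured members were higher, 3 lower and 8 within that size (median 0.43 [0.17], -0.013 at 20 CPM, F 0.16, M 0.11, percentile 100), with Dlx5 at 19.5 against 0.235 CPM (6.37 (5.44 to 7.50) [3.42]), Dlx6 at 18.1 against 0.105 CPM and Tfap2b at 7.06 CPM against 1 UMI in Root (8.08 (5.59 to 13.38) [1.12]).

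Elastic fibre genes were 8 higher, 0 lower and 10 within of 18 (median 0.45, percentile 100), led by Mfap5 at 763 against 191 CPM (2.0003 (1.97 to 2.04) [1.15], F 2.21, M 3.28) and Ltbp2. Vasoactive receptors were 5 higher, 2 lower and 7 within of 14 (median 0.36 [0.13], 0.081 at 20 CPM, F 0.22, M 0.41, percentile 99.96), with the natriuretic peptide receptor Npr1 at 130.2 against 41.9 CPM. Wnt genes were split, 5 higher, 6 lower and 13 within of 24 (median 0.053 [0.090], F 0.093, M 0.27), with Sfrp2 at 453 against 36.4 CPM (3.64 (3.56 to 3.71)) and Sfrp1 at 5.48 against 42.3 CPM. Axon guidance genes gave 5 higher, 5 lower and 10 within of 20 (median -0.022, F -0.059, M 0.14), with Sema3c, a guidance signal, at 136 against 35.0 CPM. Modulated SMC genes were 2 higher, 9 lower and 3 within of 14 (median -0.83 [-0.032], percentile 0). Proteoglycan genes had 2 higher, 6 lower and 5 within of 13 (median -0.33 [-0.035], F -0.13, M -0.18, percentile 0). Notch genes had 0 higher, 3 lower and 5 within of 8 (median -0.38 [-0.028], F -0.34, M -0.85, percentile 0.0200). Immediate-early and dissociation genes gave 1 higher, 10 lower and 12 within of 23 (median -0.41 [0.20], F -0.30, M -0.25, percentile 0), with Jun at 383 against 852 CPM. Contractile genes had 2 higher, 2 lower and 21 within of 25 (median -0.026, F -0.079, M -0.20), with Des at 27.0 against 233 CPM and Pln at 12.9 against 106 CPM. Their regulators gave 0 higher, 1 lower and 12 within of 13 (median -0.022 [0.12]). TGF-beta genes gave 0 higher, 3 lower and 23 within of 26 (median -0.086 [-0.015], percentile 0.360).

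Inflammatory genes were 1 higher, 5 lower and 4 within of 10 (median -0.25 [0.11], 0.047 at 20 CPM, F -0.15, M -0.22, percentile 0.0600), with the adhesion gene Vcam1 at 20.96 against 45.4 CPM, beside summed macrophage markers of 2.47 and 15.3 CPM. Proteases had 3 higher, 5 lower and 7 within of 15 (median 0.061 [0.16], 0.32 at 20 CPM, F -0.045, M 0.12). Growth factor genes had 2 higher, 2 lower and 11 within of 15 (median -0.080 [0.037], F -0.038, M -0.20). Lipid genes gave 2 higher, 2 lower and 6 within of 10 (median 0.19 [0.34], F 0.35, M 0.40, Apoe 173 against 583 CPM). Circadian genes had 1 higher, 3 lower and 10 within of 14 (median 0.055 [0.17], 0.12 at 20 CPM). No oxidative phosphorylation gene was outside the size (median 0.13 [0.067], F 0.13, M 0.0076). The medians of the collagens (0.0047, 0.16 at 20 CPM, F 0.37, M 0.17, 6 higher, 2 lower and 9 within of 17), BMP (0.037, F -0.040, M 0.29, 3 higher, 2 lower and 13 within of 18), heritable disease (0.031, 2 higher, 2 lower and 17 within of 21) and ion channel lists (0.012 [-0.076], F -0.074, M 0.14, 4 higher, 1 lower and 13 within of 18) turned negative under another scaling. The sex-linked list had 4 higher, 2 lower and 0 within of 6 (median 2.32, 0.27 at 20 CPM), the libraries with the smallest and largest female shares being compared. Within the 2 shared clusters 47 genes were at least 2-fold higher and 35 lower. With Root's eGFP cells alone, which share the reporter of the arch library, Tnnt2 was at -3.95 and Corin at -7.70.

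**Figure D2:**
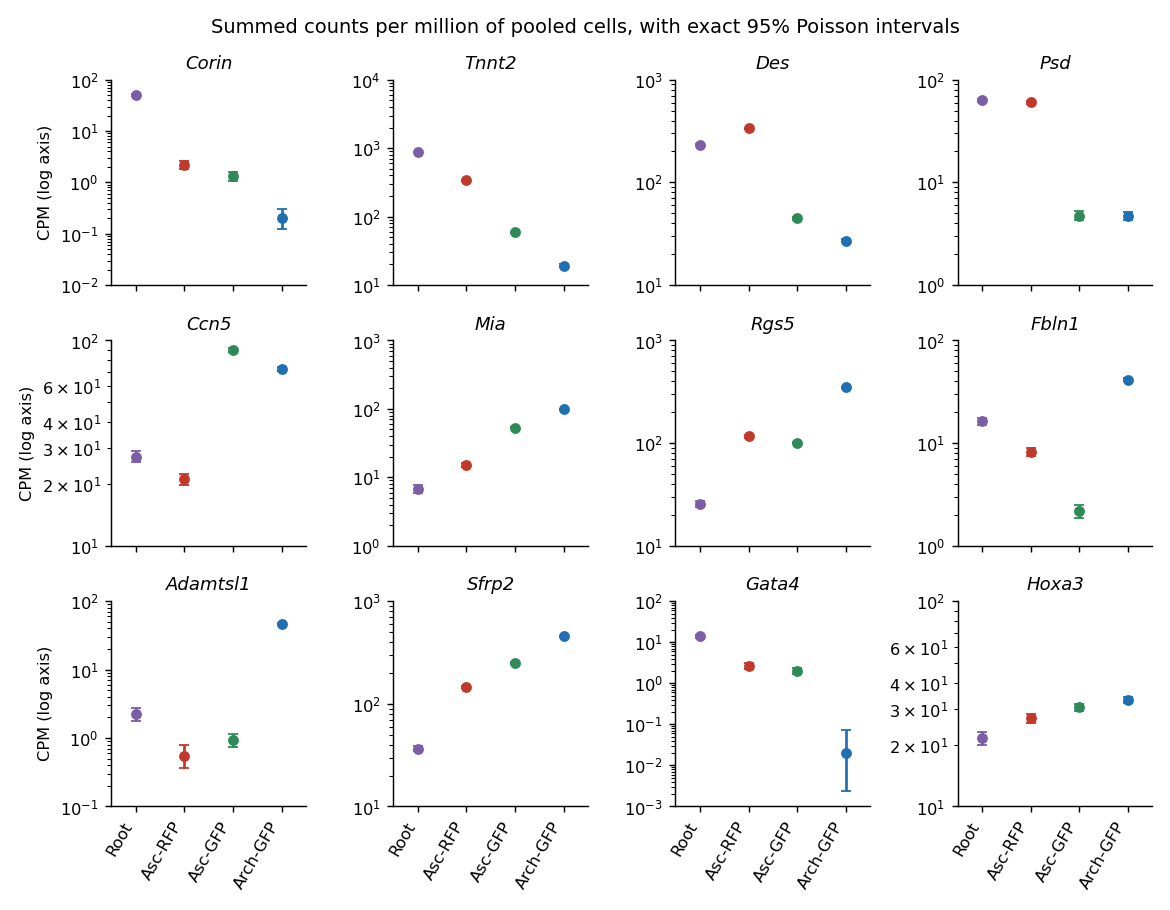
CPM (vertical axis, log scale) of 12 genes in the pooled cells of Root, Asc-RFP, Asc-GFP and Arch-GFP, with bars for 95% Poisson intervals that cover counting error only. Corin ran from 50.2 CPM in Root to 0.198 CPM in Arch-GFP and Tnnt2 from 876 to 19.2 CPM, while Sfrp2 ran from 36.4 to 453 CPM.

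Against the GFP cells of the ascending aorta, Root carried more Tnnt2 (876 against 58.8 CPM, 3.90 (3.85 to 3.94) [2.10]) and Tcf21 (5.28 against 0.107 CPM) and less Sfrp2 (36.4 against 249.8 CPM, -2.78 (-2.86 to -2.70)) and Ccn5 (27.2 against 89.6 CPM). At least 2-fold, 47 of 5793 genes were higher in Root and 36 lower. Cardiac regulators were 9 higher, 1 lower and 6 within of 16 (median 0.55, percentile 100). HOX genes had 0 higher, 5 lower and 1 within of 6 (median -0.70, percentile 0). Modulated SMC genes had 9 higher, 0 lower and 5 within of 14 (median 0.73 [0.076], percentile 100). Inflammatory genes had 4 higher, 0 lower and 5 within of 9 (median 0.47 [0.13], 0.16 at 20 CPM, percentile 100). Immediate-early and dissociation genes had 8 higher, 1 lower and 14 within of 23 (median 0.31 [0.0074], F 0.25, M 0.52, percentile 100). Elastic fibre genes had 1 higher, 4 lower and 13 within of 18 (median -0.20 [-0.12], -0.31 at 20 CPM, percentile 0.0900), with Eln at 1237 against 2271 CPM and Mfap5 at 191 against 572 CPM. Without cluster 4 the counts were 26 higher and 21 lower.

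The arch GFP cells, set against the ascending RFP cells, had more Epha3 (22.5 against 1.26 CPM, 4.16 (3.81 to 4.53)), Fbln1 (41.6 against 8.17 CPM) and Ccn5 (72.3 against 21.1 CPM) and less Des (27.0 against 335 CPM, -3.63 (-3.69 to -3.57) [-1.87]) and Tnnt2 (19.2 against 342 CPM, -4.16 (-4.22 to -4.09) [-2.65]). The counts were 45 higher and 19 lower of 5801 genes. Neural crest-associated regulators gave 11 higher, 1 lower and 7 within of 19 (median 0.79 [0.050], 0.39 at 20 CPM, percentile 100). Elastic fibre genes gave 4 higher, 1 lower and 13 within of 18 (median 0.22 [0.13], percentile 100). BMP genes gave 6 higher, 1 lower and 11 within of 18 (median 0.30 [-0.032], percentile 100). Vasoactive receptors had 5 higher, 0 lower and 9 within of 14 (median 0.14 [-0.058], -0.0027 at 20 CPM, percentile 97.6). Lipid genes had 3 higher, 1 lower and 6 within of 10 (median 0.29, F 0.50, M 0.32, percentile 100). The cardiac list had 1 higher, 4 lower and 8 within of 13 (median -0.10, percentile 0.0200), and no HOX gene of 7 left the size (median 0.12 [-0.13], 0.20 at 20 CPM). Without cluster 6, 24 genes were at least 2-fold higher.

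**Figure D3:**
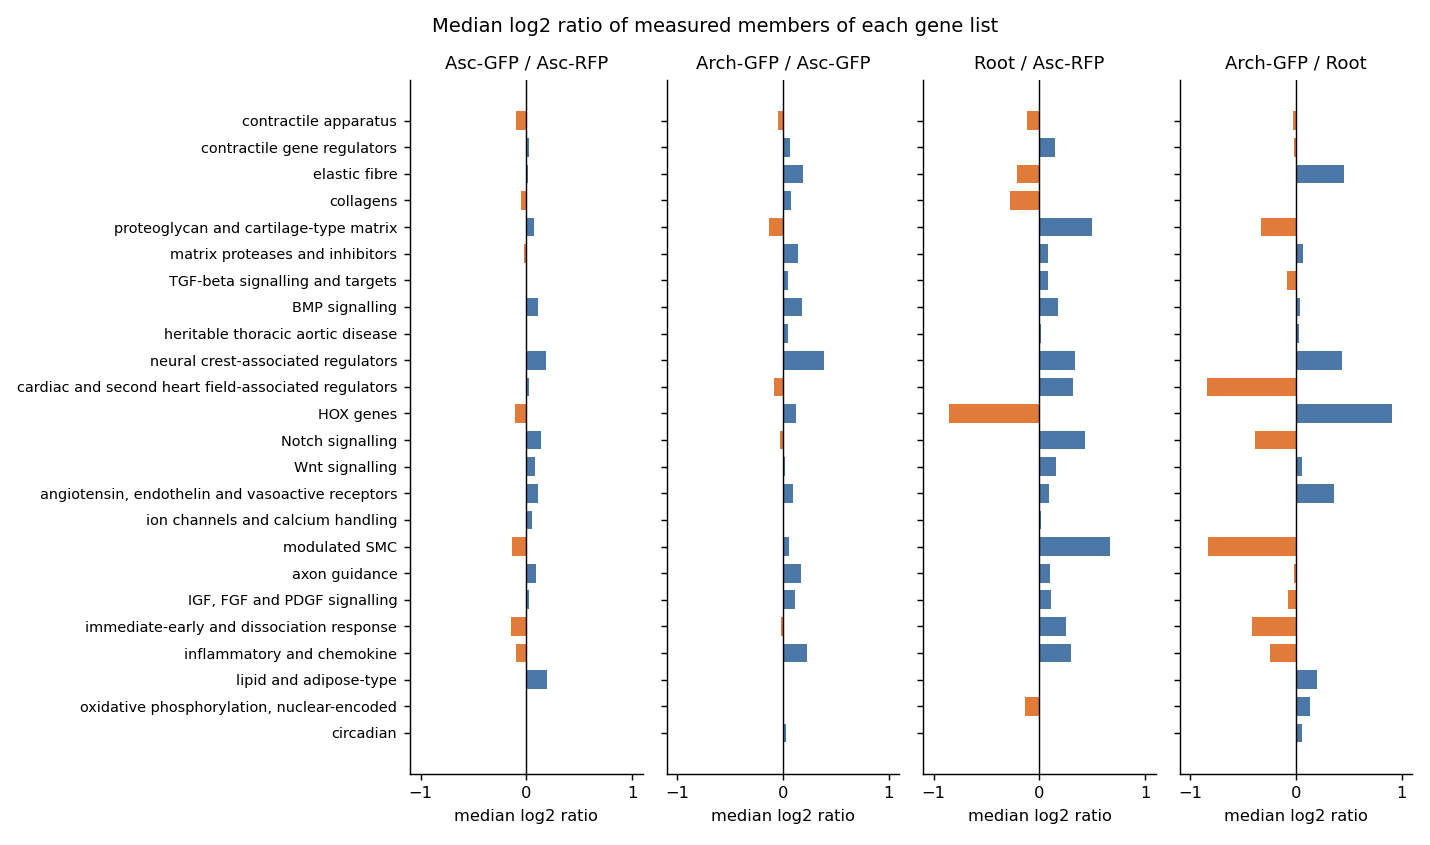
Median log2 ratio of CPM over measured members (horizontal axis) for 24 gene lists in 4 comparisons, blue for medians at or above 0 and orange below. HOX genes reached 0.90 and cardiac regulators -0.85 in Arch-GFP against Root, and the bars near 0 that the text names as turning sign under another scaling carry no direction.

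Across 5948 genes with at least 20 CPM in any library, the pooled levels were closest between Arch-GFP and Asc-GFP (Pearson r of log2(CPM + 1) 0.991, Spearman rho 0.989) and farthest apart between Arch-GFP and Root (0.960, 0.951). The others were Asc-GFP with Asc-RFP (0.987, 0.986), Root with Asc-RFP (0.981, 0.972), Arch-GFP with Asc-RFP (0.980, 0.978) and Root with Asc-GFP (0.974, 0.968). These correlations are across genes, which are not independent replicates. The reporters eGFP and tdTomato were among the genes, which adds to the distance between libraries of different colour. The order of the pairs was not computed without them.

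The reporter difference within the ascending aorta was set against the difference between the outer segments, a pair of comparisons that share no library. Across the same wider set of genes, Pearson r was 0.466 and Spearman rho 0.141, and r was 0.362 without the reporters and sex-linked genes. Root held 1935 tdTomato and 574 eGFP cells, so Arch-GFP against Root, and the score below built from it, mix segment with reporter. With only the eGFP cells of Root, r without the reporters and sex-linked genes was 0.189. Of 14 genes at least 2-fold higher in Asc-GFP, 7 were also higher in Arch-GFP than in Root, and of 23 lower ones, 16 were also lower, Tnnt2, Des and Dcn among them. Of all the genes, 60.3% were higher in Arch-GFP than in Root, so the higher genes showed no more than that share. Acan, higher in Asc-GFP, was at 35.1 CPM in Arch-GFP and 36.8 CPM in Root. A score per cell, built from the genes at least 2-fold apart between Arch-GFP and Root, had a mean 0.574 SD higher in Asc-GFP than in Asc-RFP cells after thinning (0.570 in female and 0.543 in male cells) and 0.699 SD higher unthinned. The SD is over cells, not animals, and the score also reads free RNA, which was not estimated.

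**Figure D4:**
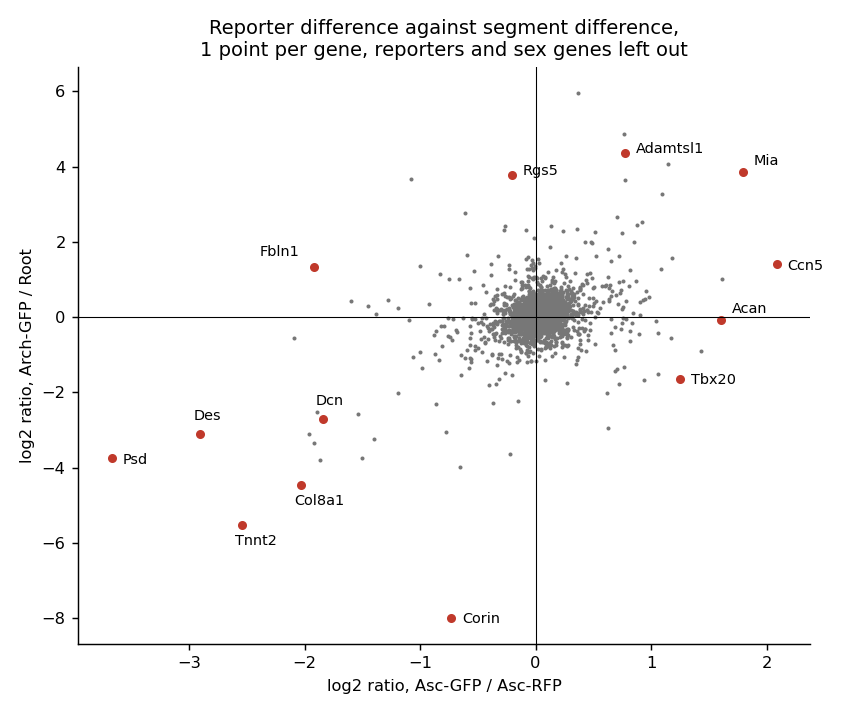
Each point is 1 gene, placed by its log2 ratio of CPM in Asc-GFP against Asc-RFP (horizontal axis) and in Arch-GFP against Root (vertical axis), reporters and sex-linked genes left out. The points spread around a positive trend with Pearson r 0.362, and Des and Tnnt2 lie low on both axes. Root held mostly tdTomato cells, so the vertical axis mixes segment with reporter.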

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

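In this part, the tests of lineage, of the sex mix and of the shallow cluster were written before their results were seen, and only that of a small cluster for Timp1 was chosen after.

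Macrophage-like and endothelial-like cells were present in the sorted libraries, a signal in data on which no comparison was made. Macrophage-like cells made up 3.345% of Root and 1.638% of Asc-RFP cells, and endothelial-like cells 1.824% of Root and 0.3475% of Asc-RFP cells. In the macrophage-like Root cells, the complement gene C1qa was at 6209 CPM (6056 to 6366), the lysozyme gene Lyz2 at 9344 CPM (9155 to 9535) and Apoe at 16482 CPM (16231 to 16735), beside Acta2 at 10206 and Myh11 at 1179 CPM. Endothelial-like Root cells had Pecam1 at 986 CPM (894 to 1085) and the mucin-like Emcn at 804 CPM (721 to 894). Contractile genes in these cells are what free RNA or doublets would leave, which was not tested.

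Root also held a signal its label does not name: 21.71% of its pooled cells carried at least 8 eGFP UMIs. In them the reporter difference of the ascending aorta (Psd, Des and Tnnt2 lower and Ccn5 higher in GFP cells) was checked inside a single library: across genes, the ratio of Root eGFP to tdTomato cells and the ratio of Asc-GFP to Asc-RFP had a Pearson r of 0.533 and a Spearman rho of 0.242, reporters and sex-linked genes left out. This is consistent with a difference between the lineages for the genes with large ratios, while by rank the agreement was weak. An unequal mix of the sexes would have shrunk the ratios within a sex, yet the median share left was 1.01 (27 genes, 0.908 to 1.098), and leaving out the shallow cluster left 0.999. What stays open is how much of the difference belongs to the animals, since each library pools at least 2 animals, having cells of both sexes, and the same animals may have given both colours.

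For 3 genes the female and male cells pointed opposite ways, which is what brought them here, and the differences between the sexes were not tested. Cxcl12, a chemokine, was higher in Root than in Asc-RFP in female cells (91.9 against 57.9 CPM, log2 ratio 0.67 (0.58 to 0.76)) and lower in male cells (25.4 against 40.9 CPM, log2 ratio -0.69 (-0.99 to -0.40)), a gap of 1.355. Timp1, an inhibitor of matrix proteases, was higher in Arch-GFP than in Root in female cells (44.6 against 9.55 CPM, log2 ratio 2.22 (2.04 to 2.41)) and lower in male cells (11.6 against 19.4 CPM, log2 ratio -0.74 (-1.07 to -0.38)), a gap of 2.957. Of the Timp1 UMIs, 66.5% in female and 10.4% in male Arch-GFP cells lay in 18 and 19 cells of cluster 9, led by Timp1 and Vcam1. Without that cluster the ratios were 0.78 (0.54 to 1.01) and -0.89 (-1.23 to -0.53), so much of the female excess came with these few cells. Igfbp5, an IGF-binding protein, had 26.6 against 9.06 CPM, log2 ratio 1.55 (1.35 to 1.76) in female and 25.0 against 37.5 CPM, log2 ratio -0.59 (-0.83 to -0.34) in male cells of the same libraries, a gap of 2.139. Root had only 297 male cells, with 105 UMIs of Cxcl12, 80 of Timp1 and 155 of Igfbp5, and sex stands in each library for an unknown number of animals.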

How the results depend on the processing

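Alternatives by sex, by cluster and by Root reporter were added after the data were seen, and the others were written beforehand. Leaving out a replicate could not be done with 1 library per group. No paired analysis was possible because the labels give no animals shared between libraries. Of 1750 alternative ratios of the genes ranked farthest apart, list members not counted, 1338 lay inside the gene's counting interval, 410 lay outside with the same sign, and 2, both of Lum, reversed. Lum in Root against Asc-RFP went from 2.71 to -0.27 without the cluster led by Lum and Dcn and to -0.38 within shared clusters, Lum being a gene that leads this cluster. Among the list members Cxcl12, Timp1 and Igfbp5 reversed in male cells. All 120 alternative correlations between libraries stayed within 0.05, and in 22 of 22 settings Arch-GFP with Asc-GFP was the closest pair and Arch-GFP with Root the farthest. No setting left the reporters out of the correlated genes, so whether this order holds without them was not tested.

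Counts of genes at least 2-fold apart stayed within 1.5 times of the chosen setting in 203 of 258 cases. The floor moved every count, by its construction. With no floor but 10 UMIs the counts were 484 higher and 482 lower for Asc-GFP against Asc-RFP, 710 higher and 325 lower for Arch-GFP against Asc-GFP, 627 higher and 555 lower for Root against Asc-RFP, 1164 higher and 800 lower for Arch-GFP against Root, 719 higher and 656 lower for Root against Asc-GFP and 878 higher and 465 lower for Arch-GFP against Asc-RFP. At 100 CPM they were 2 higher and 4 lower, 2 higher and 2 lower, 7 higher and 6 lower, 23 higher and 19 lower, 11 higher and 10 lower and 10 higher and 7 lower in the same order, fewer because fewer genes were tested.

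Within shared clusters there were 6 higher and 7 lower for Asc-GFP against Asc-RFP, 12 higher for Arch-GFP against Asc-GFP, 13 higher and 12 lower for Root against Asc-RFP, 47 higher and 35 lower for Arch-GFP against Root, 20 higher and 16 lower for Root against Asc-GFP and 13 higher and 9 lower for Arch-GFP against Asc-RFP. Leaving out the arch cluster, led by Adamtsl1 and Prss12, gave 9 higher genes against Asc-GFP and 24 against Asc-RFP. Without the Lum and Dcn cluster there were 22 higher and 14 lower for Root against Asc-RFP, 38 lower for Arch-GFP against Root and 26 higher and 21 lower for Root against Asc-GFP. In each of these the excluded or split clusters are unequally filled by the libraries. Male cells alone gave 3 lower for Arch-GFP against Asc-GFP. With only 297 male Root cells, they gave 99 higher and 66 lower for Root against Asc-RFP. For Arch-GFP against Root they gave 137 higher and 121 lower, and for Root against Asc-GFP 100 higher and 68 lower. The cause was not tested. With only the eGFP cells of Root, 48 genes were lower than in Asc-RFP. All deposited barcodes gave 28 lower for Asc-GFP against Asc-RFP, 83 higher for Root against Asc-GFP and 32 lower for Arch-GFP against Asc-RFP, and all classes of cells gave 27 and 82 for the former 2. Both settings let in macrophage-like, endothelial-like and low-UMI cells, and which of these moved the counts was not tested.

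The correlation between the comparisons that share no library (0.466) was 0.751 with all barcodes, 0.751 with all classes, 0.230 with no floor, 0.671 at 100 CPM, 0.329 in thinned cells and 0.257 with only eGFP cells of Root. Without reporters and sex-linked genes it was 0.362, and in the same settings 0.761, 0.759, 0.217, 0.465, 0.346 and 0.189, so that thinning made little difference there. What sets the others apart was not tested. The score per cell gave 1.07 SD with the fewer genes at least 4-fold apart, against 0.574. Pooled shares were 76.1% of Root, 72.8% of Asc-GFP, 64.4% of Asc-RFP and 78.5% of Arch-GFP with no barcode filter. They were 99.9%, 98.2% and 100% of the latter 3 with a stricter filter. These follow from which barcodes enter. At the finer Leiden resolution, which leaves out other clusters, 97.98% of Arch-GFP was pooled.

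Of 200 alternative list medians, by TMM or a member floor of 20 CPM, 190 stayed within 0.25 of the chosen setting, among them medians near 0 that took the other sign. With members at 20 CPM or more, so with fewer members, the sex-linked median was -0.10 for Asc-GFP against Asc-RFP, -0.21 and so reversed for Arch-GFP against Asc-GFP, -0.53 for Root against Asc-RFP and 0.27 for Arch-GFP against Root. The modulated SMC median was 0.32 for Arch-GFP against Asc-GFP. For Arch-GFP against Root it was 0.32 for proteases, -0.013 for neural crest-associated regulators (Dlx5, Dlx6 and Tfap2b fell under the floor), -0.40 for cardiac regulators, 0.081 for vasoactive receptors and 0.047 for inflammatory genes. Medians within clusters and by sex, which that tally leaves out, moved further. Within shared clusters, for Root against Asc-RFP, modulated SMC genes went from 0.67 to -0.070 and proteoglycan genes from 0.50 to 0.077. For Arch-GFP against Root, modulated SMC genes went from -0.83 to -0.032, immediate-early genes from -0.41 to 0.20, inflammatory genes from -0.25 to 0.11 and Notch genes from -0.38 to -0.028. There proteoglycan genes went from -0.33 to -0.035, HOX genes from 0.90 to 0.43, cardiac regulators from -0.85 to -0.57 and neural crest-associated regulators from 0.43 to 0.17. In female and male cells of the same libraries, neural crest-associated regulators were at 0.16 and 0.11, collagens at 0.37 and 0.17, HOX genes at 0.61 and 0.995, cardiac regulators at -0.68 and -1.13, BMP genes at -0.040 and 0.29 and Notch genes at -0.34 and -0.85. For Root against Asc-RFP, contractile genes were at -0.14 and 0.14 and inflammatory genes at 0.27 and -0.0024. Depth limits what a count of 0 can exclude: 3 UMIs were 0.0785 CPM in Root and 0.0298 CPM in Arch-GFP.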

Other observations

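The tests of lineage-wide occurrence and of leaking for the shallow cluster, and of a single animal, of doublets and of genes outside the clustering for the arch cluster, were chosen only after the result was seen.

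Inside Root, several genes differed between eGFP and tdTomato cells as they did between the GFP and RFP cells of the ascending aorta. Ccn5 was higher in eGFP cells (57.2 against 18.1 CPM, log2 ratio 1.66 (1.47 to 1.85)), as were Krt18 (25.5 against 8.88 CPM, log2 ratio 1.52 (1.24 to 1.80)), the secreted protein Ccdc3 (1.11) and Sfrp1 (1.03). Lower were Psd (6.66 against 77.4 CPM, log2 ratio -3.54 (-3.97 to -3.14)), Des (34.1 against 296 CPM, log2 ratio -3.12 (-3.30 to -2.94)), Hand2os1 (-2.32), Tnnt2 (296 against 1024 CPM, log2 ratio -1.79 (-1.85 to -1.73)), Rgs5 (-1.78, against -0.21 in the ascending aorta), Gpc3 (-1.51), Cxcl12 (-1.23), Dcn (-2.07) and Lum (-2.49). Thbs1, a matricellular protein, was higher here (0.87, but 0.072 in female cells) and lower in Asc-GFP than in Asc-RFP (-1.86). The reporter groups filled different clusters, since 354 of 574 eGFP cells but 697 of 1935 tdTomato cells lay outside cluster 4. Without that cluster the ratio was -1.16 for Tnnt2, -1.05 for Dcn, -1.001 for Lum, -0.58 for Cxcl12 and -2.10 for Thbs1, which so turned. By the 2-fold rule 5 of 5752 genes were higher and 19 lower, the reporters included. Of 9 genes higher in Asc-GFP than in Asc-RFP, 7 were also higher here, and of 10 lower ones 9 were also lower, where 56.1% of all genes were higher in eGFP cells. Across genes r was 0.533 and Spearman rho 0.242. In female cells only, r between the 2 sets of ratios was 0.537, and with an eGFP threshold of 20 UMIs 0.532. Of the HOX genes, 3 of 4 were lower in eGFP cells (median -0.94). Contractile genes gave 1 higher and 2 lower of 25, and proteoglycan genes 1 higher and 5 lower of 14 (median -0.35).

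A cluster of 1152 Arch-GFP cells, led by Adamtsl1, Prss12, Tfap2b and Dlx6, was set against the other pooled arch cells in genes outside the 2000 variable genes that built the clusters. The homeobox gene Msx2 (48.6 against 1.89 CPM, 4.68), the BMP antagonist noggin (Nog, 11.3 against 0.806 CPM, 3.81), the endothelin receptor Ednra (41.7 against 3.48 CPM, 3.58) and the guidance ligand Slit2 (7.69 against 2.02 CPM, 1.93) were higher. Among such genes, elastic fibre genes had 8 of 12 higher and 0 lower (median 0.61), collagens 5 of 11 higher and 1 lower (median 0.45), neural crest-associated regulators 6 of 11 higher and 1 lower (median 0.61) and axon guidance genes 10 of 20 higher and 3 lower (median 0.53). Contractile genes had 1 of 18 higher and 3 lower (median -0.16) and Notch genes 1 of 8 higher and 4 lower (median -0.48), with Notch3 at 12.4 against 20.1 CPM, -0.69. Acta2, itself a variable gene, was at 13708 against 22714 CPM, -0.73. Markers of other cell types moved with the cluster, with mean log2 ratios against the other clusters of 0.87 for pericyte, 0.43 for chondrocyte and -0.50 for SMC markers. Neuron markers, none of which counted as detected, were at 0.45. Lower than the SMC markers were macrophage (-2.86), endothelial (-0.99) and cardiomyocyte markers (-0.90). The first 2 are not particular to this cluster, since the other clusters include the macrophage-like and endothelial-like ones. Cluster 0, for example, had -3.11 for macrophage and -1.08 for endothelial markers.

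Several origins were weighed for the arch cluster. Cells of a single animal would be of 1 sex, but 23.3% (20.6 to 26.1) of its sexed cells were of the rarer sex. Doublets were not excluded: the ratio of median UMIs to other arch cells was 0.946, but arch cells with both sex signals were not deeper either (12093 against 13323 and 13592 UMIs), so depth says nothing here. The 7 measured HOX genes, all outside the variable genes, had a median of 0.57 (range -0.29 to 0.95), led by Hoxa5 (12.3 against 6.38 CPM, 0.95). A subset that also differs by position would show this, but the value does not single it out. Some lists not chosen for position reached like medians among such genes, as elastic fibre genes (0.61) and proteases (0.58), while others were lower. It stays open whether doublets play a part, whether the cells lie at 1 place in the arch and whether they occur in arch cells without eGFP, which were not sampled.

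Cluster 3 was nearly confined to the GFP libraries and shallow, with a median of 6549 UMIs against 13618 in other Asc-GFP cells and 4989 against 14390 in Arch-GFP. After thinning, the cytoskeletal actin Actb was higher in it (1.001 in Asc-GFP and 1.24 in Arch-GFP), Acta2 slightly higher (0.38 and 0.35) and Myh11 lower (-0.48 and -0.45). Whether depth alone set these cells apart is not decided by this. Thinning hardly changes the CPM expected from summed cells, and the cells were grouped by expression, with Actb among the cluster's leading genes. Cluster 3 held 16.3% of Asc-GFP and 26.4% of Arch-GFP cells but 1.05% of the Root eGFP cells (6 of 574, 0.385 to 2.26) and 1.30% of Asc-RFP cells. The cluster was singled out for lying in the GFP libraries and held only 21 Root cells, so these shares say nothing about the lineage. The reporters were not kept out of the main clustering and eGFP is among the cluster's 10 leading genes, so part of its confinement may be built in. A clustering without the reporters was run for the gene counts and correlations, but how the libraries filled its clusters was not compared. Leaking cells would have a larger mitochondrial share, yet the cluster's ratio to other cells was at most 0.920. Barcodes over 10% mitochondrial UMIs (1112 in Asc-GFP and 1091 in Arch-GFP) had been removed before clustering, so this is only weak evidence against leaking. The cause stays open, the lineage and a step of sorting or handling the GFP samples among those that could not be tested.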
